A study of Glycine max with 4 samples.

How the data were processed

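Nuclei from hand-dissected soybean embryos (cultivar Williams 82, early maturation) were purified on a density gradient, treated with the Tn5 transposase and turned into libraries with 10 PCR cycles, per the labels' protocols. The labels name 2 biological replicates, each with a single-end sample and a paired-end sample, so each group had 2 samples. Only paired-end data were used by the authors, per the series' design text. The submitters' processing notes name the aligner Bowtie2 2.3.4.1, SAMtools, HOMER and bedtools, without their role or order. The genome build, the peak-calling settings, the filters and the handling of the transposase offset are not given in the sources used here.

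The authors deposited 1 peak list for the series, with 3 columns that give the sequence, start and end of each peak in base pairs, the starts counted from 0. The name of the list describes it as an intersection, but how the replicates were joined is not given in the sources used here. The deposited list holds no count, score, signal or p-value. Depth, replicate error and the height of peaks were therefore unknown, and the precision of each peak could not be given. If the list is an intersection of both replicates, its edges can differ from those in either replicate, and regions open in 1 replicate alone would not appear.

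Comparisons with genes had been planned before the data were examined: the share of peaks in promoters, peak density against gene density, fixed gene lists, DNA motifs, GC content and duplicated gene pairs. None was run. No genome sequence was used, and the gene table used here was on assembly Glycine_max_v4.0. The fit of its coordinates was checked by shifting the peaks. Without a shift, 12.9% of chromosomal peak midpoints lay within 500 bp of an edge of a protein-coding gene, and with 14 shifts of 2 to 200 kb in either direction the share was 11.7% to 13.1%. Further, 54 peaks on 4 chromosomes lay beyond the last gene of the table. No coordinates of the table were used. The rule for named genes fixed beforehand asked for members of gene lists and for the 5 widest peaks with their nearest gene, of which only the positions of the widest peaks could be given. All other regions were chosen after their values were seen, and the comparisons that are reported were chosen after the list had been examined.

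Peak positions were analysed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plotted with matplotlib 3.10.9. Coordinates were converted to count from 1. The span of a chromosome was taken as the end of its last peak, which is a lower bound of its length. The outer parts were the first and last 25% of the span, and the inner part was the rest. Peaks were assigned by their midpoint. Density ratios (on a log2 scale), differences in median width, differences in the share of peaks at 306 bp and differences between the start and end of chromosomes were tested with two-sided sign-flip permutation tests over 20 chromosomes with 100000 flips, and Benjamini-Hochberg values were computed over these 4. The sparsest and fullest stretches were found by moving a window of 10 Mb in steps of 100 kb.

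Local clustering was the share of neighbouring midpoints within 5 kb, set against 1000 placements of each midpoint at random within its own window of 1 Mb. Clusters were chains of peaks with gaps of at most 10 kb, called dense with at least 8 peaks. Wide peaks had at least 2 kb, and their location was compared by Fisher's exact test. Shares carry 95% exact (Clopper-Pearson) binomial intervals. Scaffold and chromosomal widths were compared by a permutation test with 10000 resamples over peaks. The random seed was 20240.

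The procedures were tested on simulated lists of 10719 peaks placed on the real chromosome spans, with 20 lists per setting. Except in the last setting, peaks were placed independently of one another. Widths were drawn from real chromosomal peaks under 2 kb, and fewer flips and placements were used than for the real list. Even placement gave a mean outer to inner ratio of 1.00 and a clustering fold of 0.991, with 0 lists called for any of the 3 measures. That does not show how often lists with clustered peaks would be called falsely. An outer density set 2-fold higher was recovered as 2.01 and called in 20 of 20 lists. Inner peaks set 50 bp wider were recovered as 49.6 bp wider and called in 20 of 20. Setting 1 in 5 peaks within 5 kb of another gave a clustering fold of 4.17, called in 20 of 20 lists, while the density and width tests each called 1 of these lists. Alternatives covered the set of peaks used, the extent of the outer parts, the placement window, the neighbour distance, the width of wide peaks and the gap joined into clusters.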

Results

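Open chromatin was profiled in embryos of the soybean (Glycine max) cultivar Williams 82, the cultivar from which the soybean reference genome was built. The embryos were dissected by hand at early maturation, from seeds 6 to 7 mm long. At this stage the cotyledons fill with storage protein and oil. The assay was ATAC-seq, in which the Tn5 transposase inserts sequencing adapters mainly where DNA is not covered by nucleosomes, so that stretches rich in insertions mark accessible chromatin. Each reaction used 50000 purified nuclei. The 2 biological replicates were each sequenced in a single-end run and in a paired-end run, which gave 2 samples per group. Only the paired-end runs were used by the authors, per the series' design text.

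The series had 1 peak list, which named no replicate and held positions without heights, scores or read counts. The read depth behind each peak was therefore unknown, and peaks carried no replicate error. No comparison between replicates or between runs could be made. The design held 1 tissue at 1 stage, so the question addressed was where in the genome accessible chromatin lay. Positions are given as in the deposited list, counted from 1, on a genome build that is not given in the sources used here. No gene was assigned to any peak, because peaks lay no closer to the genes of the table used here than after being shifted, so its coordinates were not taken to fit.

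The list held 11436 peaks that did not overlap and together covered 6.10 Mb. The 20 chromosomes carried 10719 of them, which covered 0.598% of the 947 Mb between the chromosome starts and the last peak of each chromosome. The other 717 peaks lay on 296 unplaced scaffolds, 6.27% of the list (95% exact binomial interval 5.83 to 6.73). Measured to their last peaks, these scaffolds spanned 15.1 Mb. That is a lower bound which leaves out scaffolds without a peak, so no scaffold density was computed. Chromosome 18 had 656 peaks and chromosome 16 had 365, the highest and lowest numbers. Density averaged 11.4 ± 1.19 peaks per Mb (SD, n = 20 chromosomes), from 9.57 on chromosome 20 to 13.8 on chromosome 11. Here and below, chromosomes are parts of a single peak list and not biological replicates, and intervals on shares cover counting error only. The intervals treat peaks as independent, although peaks lay in clusters, so they may be too narrow.

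Peaks were concentrated toward chromosome ends. The outer 25% at each end of a chromosome held 15.4 ± 1.95 peaks per Mb and the inner part 7.41 ± 1.75 (SD, n = 20 chromosomes). The ratio of outer to inner density averaged 2.19 ± 0.63 and was above 1 on 20 of 20 chromosomes. It was highest on chromosome 4 at 3.72, where the outer parts held 17.7 and the inner part 4.75 peaks per Mb. It was lowest on chromosome 13 at 1.08. The difference from an even density had a two-sided sign-flip permutation p of 1e-05, the smallest that 100000 flips can give, and a Benjamini-Hochberg value of 4e-05 over the 4 permutation comparisons made across chromosomes. Density fell from 17.5 ± 4.84 peaks per Mb in the first of 20 equal bins to 5.32 ± 2.34 in the bin centred at 52.5% of the span, and stood at 19.2 ± 5.14 in the last bin. Whether reads could be placed uniquely as often in the inner part as in the outer parts was not tested. The gradient is therefore one of called peaks, and how much of it reflects accessible chromatin cannot be told here.

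**Figure D1:**
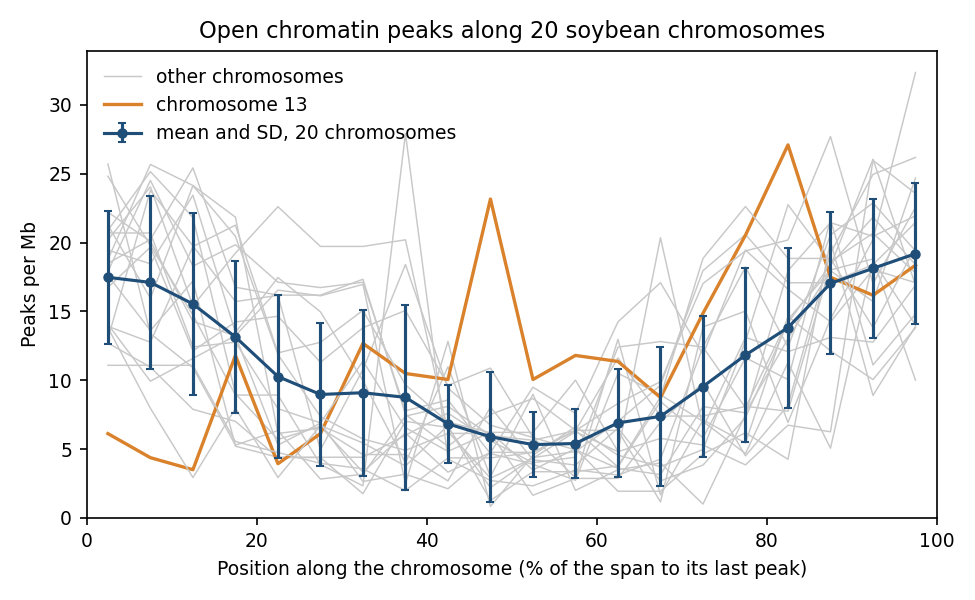
Peaks per Mb (vertical axis) in 20 equal bins along each chromosome, plotted by position as a percentage of the span to its last peak (horizontal axis). Grey lines are single chromosomes, the orange line is chromosome 13, and blue points with bars are the mean and SD of 20 chromosomes, which fall from 17.5 in the first bin to 5.32 at 52.5% of the span. Chromosome 13 starts low, at 6.12, and holds 23.2 peaks per Mb in the bin centred at 47.5%.

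On some chromosomes the start and the end differed in density. On chromosome 13 the first 25% held 5.94 peaks per Mb and the last 25% held 19.9. Chromosome 19 had 8.71 at the start and 21.4 at the end, chromosome 20 had 7.12 and 18.8, and chromosome 3 had 8.59 and 18.9. Chromosomes 6, 17 and 15 were denser at the start, with 19.5 against 10.7, 20.3 against 13.3 and 15.9 against 10.7 peaks per Mb. Across chromosomes the start minus end difference averaged -1.30 ± 6.56 peaks per Mb (SD, n = 20), with the start denser on 11, and it did not pass the test (two-sided sign-flip permutation p = 0.39, Benjamini-Hochberg value 0.39). Differences of opposite sign cancel in this test. It asks whether starts are denser than ends in general, and not whether the ends of single chromosomes differ.

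The sparsest stretch of 10 Mb lay away from both ends on most chromosomes. It held 26 peaks on chromosome 10, between 24.5 and 34.5 Mb, and 26 on chromosome 15, between 26.5 and 36.5 Mb. Chromosome 19 had 29 peaks between 11.4 and 21.4 Mb, and chromosome 20 had 29 between 21.1 and 31.1 Mb. On chromosome 13 the sparsest stretch was close to the start, between 3.1 and 13.1 Mb, and its 54 peaks were nearly as many as the 58 of chromosome 11. The fullest stretch of 10 Mb was the start of chromosome 4, with 233 peaks. Chromosome 10 had the widest contrast between its fullest and sparsest stretches at 7.81-fold, and chromosome 8 the smallest at 3.22-fold.

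Long stretches had no peak at all. The longest ran from 32927829 to 35292951 on chromosome 15, a length of 2.37 Mb. It was followed by 2.14 Mb on chromosome 2, from 21724673 to 23863971, and by 2.11 Mb on chromosome 20, from 21143772 to 23254557. In total 52 stretches on chromosomes exceeded 1 Mb, and the peak that closed the stretch lay in the inner part of the chromosome in 47 of them. Whether reads could be placed uniquely in these stretches was not tested.

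**Figure D2:**
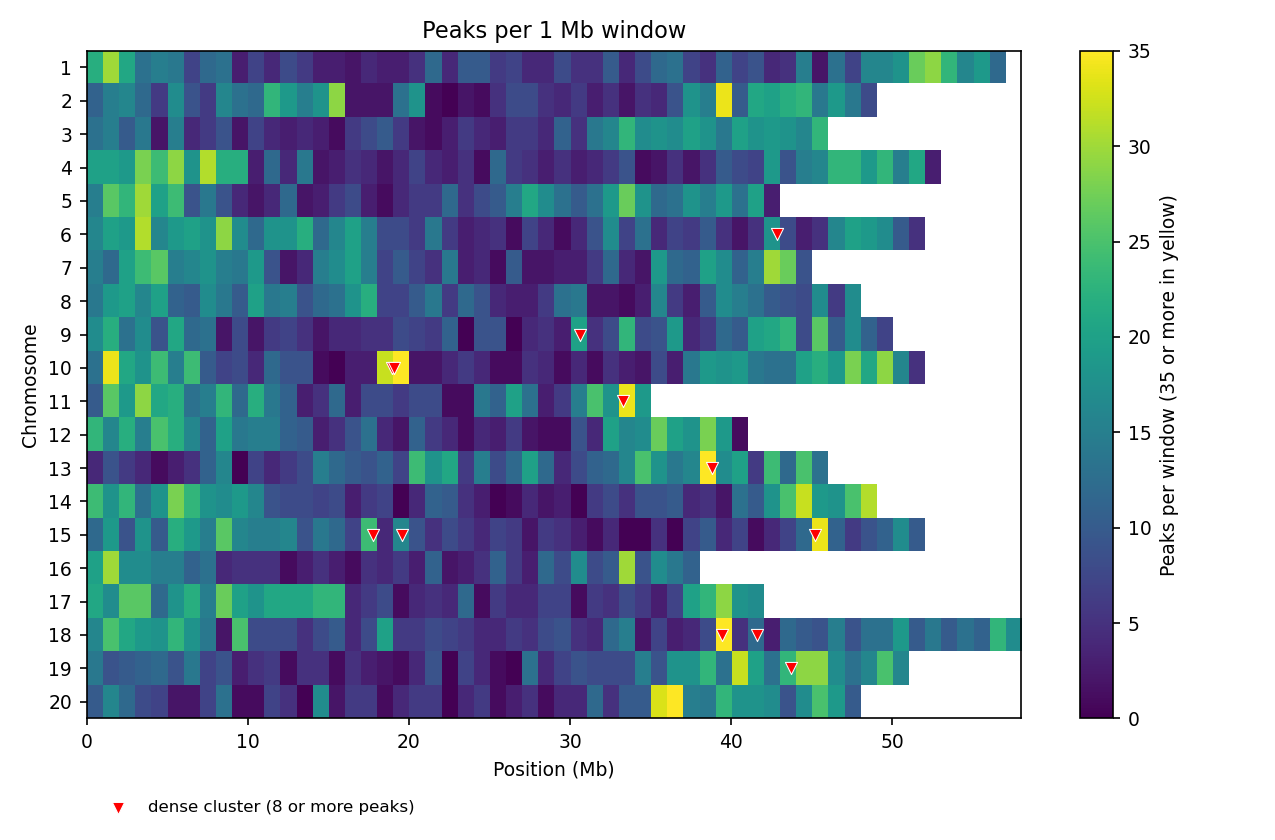
Number of peaks in each window of 1 Mb (colour, from 0 to 35, with higher counts drawn as 35) along the 20 chromosomes (vertical axis), by position in Mb (horizontal axis). Red triangles mark the 12 dense clusters on chromosomes. Windows are emptier in the middle of most chromosomes, and the fullest, with 49 peaks, is on chromosome 18. The last window of each chromosome is drawn at full width but ends at the last peak.

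The 955 windows of 1 Mb held a median of 10 peaks, with a variance 5.41 times the mean, and 15 windows were empty. These values count the last window of each chromosome as a full one, although it ended at the last peak and was shorter. The window with most peaks was on chromosome 18 between 39 and 40 Mb, with 49, followed by 44 on chromosome 13 between 38 and 39 Mb and 39 on chromosome 10 between 19 and 20 Mb. Peaks also gathered over short distances within such windows. Of 10699 pairs of neighbouring peaks, 1735 had midpoints within 5 kb, which is 16.2%. Placing each peak at random within its own window of 1 Mb gave 7.54% ± 0.245 (SD over 1000 placements), with a range of 6.78% to 8.53%. The observed share was 2.15-fold higher, with a two-sided permutation p of 0.002, the smallest that 1000 placements can give. When peaks separated by at most 10 kb were joined, 6468 peaks (56.6%) stood alone and 4968 (43.4%) fell into groups.

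The joined peaks formed 15 dense clusters, each with at least 8 peaks, of which 12 were on chromosomes and 3 on scaffolds. They held 247 peaks, including 34 of at least 2 kb. The largest was on chromosome 10 from 18891289 to 19034537, with 42 peaks that covered 43.8% of 143 kb. A cluster of 27 peaks followed it after 12.6 kb, from 19047175 to 19109764. The pair together held 69 peaks over 218 kb. On chromosome 18, from 39360424 to 39462023, 40 peaks covered 42.2% of 102 kb, with a median width of 783 bp. On chromosome 13, from 38796768 to 38859321, 25 peaks covered 52.4% of 62.6 kb, with a median width of 939 bp. Chromosome 15 had 3 dense clusters, with 15 peaks from 17745402 to 17781764, 9 from 19577063 to 19603464 and 13 from 45157984 to 45209299. The most fully covered was on chromosome 19 from 43722129 to 43746708, where 8 peaks with a median width of 2372.5 bp covered 78.7%. The number of dense clusters depended on the settings: it was 10 when only gaps of up to 5 kb were joined, 23 with gaps of up to 20 kb, 7 when peaks within 1 kb were first merged and 8 among the peaks at or above the median width.

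**Figure D3:**
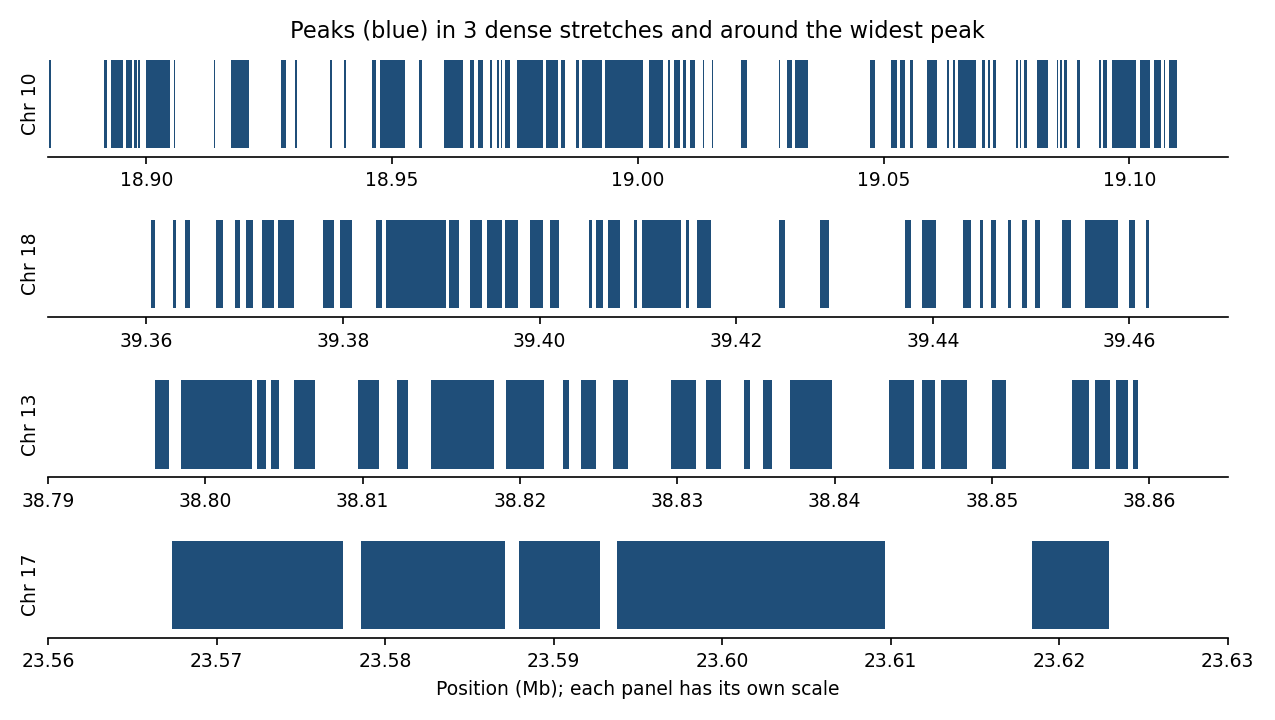
Peaks drawn to scale as blue blocks along parts of chromosomes 10, 18, 13 and 17, by position in Mb, each panel with its own horizontal scale and no vertical scale. The panel of chromosome 10 holds 2 dense clusters of 42 and 27 peaks, those of chromosomes 18 and 13 hold clusters of 40 and 25 peaks, and that of chromosome 17 holds the widest peak among 5 peaks that cover 79.0% of their stretch.

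Peak widths ran from 2 to 15877 bp, with a median of 458 bp and quartiles of 306 and 601 bp. Exactly 306 bp was the width of 1757 peaks, 15.4% of the list (95% exact binomial interval 14.7 to 16.0). A width of 308 bp was found 204 times and a width of 307 bp 11 times. From 309 to 381 bp there were 5.78 peaks per bp of width, against 58.1 from 382 to 388 bp. Widths under 306 bp belonged to 1408 peaks (12.3%, interval 11.7 to 12.9), of which 100 were under 100 bp.

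**Figure D4:**
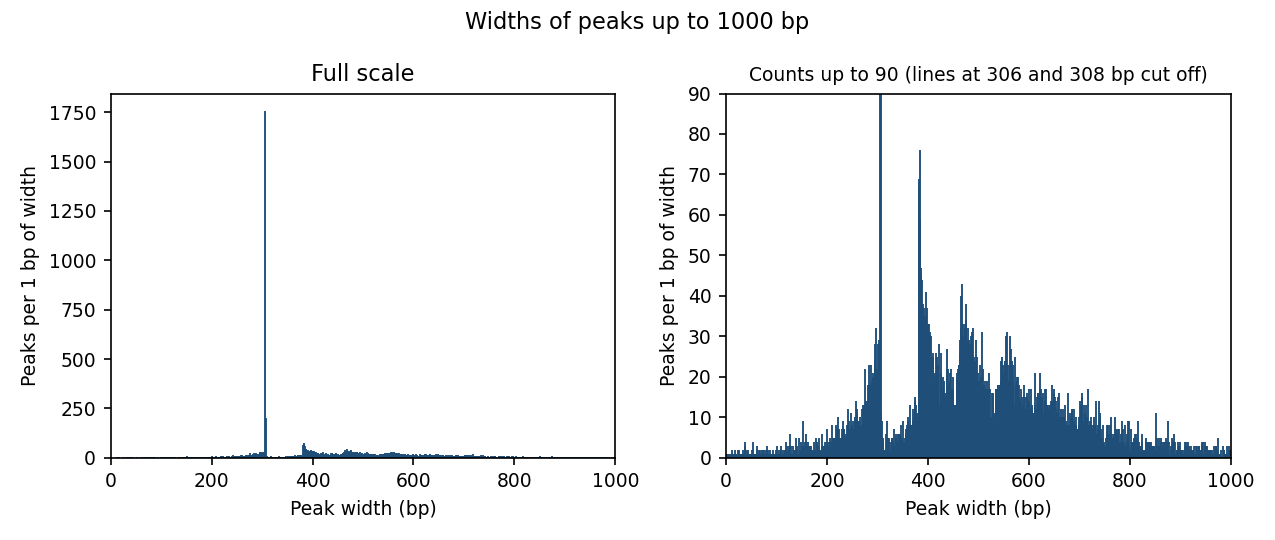
Number of peaks (vertical axis) at each width in bp (horizontal axis), for widths up to 1000 bp. The left panel shows all counts, with 1757 peaks at 306 bp, and the right panel ends at 90 peaks, so that the lines at 306 and 308 bp are cut off and the rise from 9 peaks at 381 bp to 67 at 382 bp can be seen.

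The 5 widest peaks lay on chromosomes 17, 12 and 10. The widest ran from 23593785 to 23609661 on chromosome 17, with 15877 bp. Another of 10127 bp lay before it, from 23567370 to 23577496, with other wide peaks between them. Both belonged to a run of 5 peaks, each of at least 2 kb, that covered 79.0% of the 55.6 kb from 23567370 to 23622950. On chromosome 12, peaks of 12304 and 11810 bp ran from 24272360 to 24284663 and from 39183682 to 39195491. The next was on chromosome 10, from 17196358 to 17205346, with 8989 bp. These positions lay at 56.8% of the span of chromosome 17 for the widest peak, at 60.6% and 97.8% of chromosome 12, and at 33.4% of chromosome 10.

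A larger share of wide peaks than of other peaks lay in the inner part of chromosomes. Of 108 chromosomal peaks of at least 2 kb, 62 were in the inner part (57.4%) and 46 in the outer parts. Of the other peaks, 3431 were in the inner part (32.3%) and 7180 in the outer parts. The inner part and the outer parts were equal in length, so the contrast came mainly from fewer other peaks in the inner part. Fisher's exact test gave a two-sided p of 1.3e-07, although peaks in the same run are not independent. Over all peaks, the median width was 441.6 bp in the outer parts and 465.6 bp in the inner part, averaged over chromosomes. The inner median was higher by 23.95 ± 30.6 bp (SD, n = 20 chromosomes) and was the larger on 16 of 20 (two-sided sign-flip permutation p = 0.0028, Benjamini-Hochberg value 0.0037). The largest differences were 76 bp on chromosome 6 and 74 bp on chromosome 10, and on chromosome 13 the inner median was below the outer one, with a difference of -36 bp. The share of peaks of exactly 306 bp went the other way, with 17.4% in the outer parts and 12.8% in the inner part. This difference of 4.62 ± 3.80 percentage points had the same direction on 18 of 20 chromosomes (two-sided sign-flip permutation p = 0.00014, Benjamini-Hochberg value 0.00028).

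Scaffold peaks were wider than chromosomal peaks, with a median of 495 bp (quartiles 378 and 693) against 452 bp (quartiles 306 and 596). The difference of 43 bp had a two-sided permutation p of 0.0012 with 10000 resamples over peaks, which are not independent replicates. A width of 306 bp was found in 5.02% of scaffold peaks (36 of 717, 95% exact binomial interval 3.54 to 6.88) and in 16.1% of chromosomal peaks (1721 of 10719, interval 15.4 to 16.8). Of the 296 scaffolds with peaks, 150 had 1 peak. Scaffold 21 had 32 peaks over 3.55 Mb and scaffold 86 had 30 over 0.157 Mb, measured to the end of the last peak, which is a lower bound of the scaffold's length.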

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

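All alternatives here were chosen after seeing the data, because none of the planned ones was run. Those for promoters, gene density, gene lists, motifs, GC content and duplicated pairs were not run, since no genome or annotation shown to fit the peak coordinates was used. Leaving out a replicate was not possible either. No paired analysis was possible because the list holds 1 set of peaks and names no replicate. Merging peaks within 150 bp, as planned, changes nothing, since the smallest gap is 304 bp.

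Of 45 alternatives for 8 results, 41 kept direction and side of the threshold or, without a test, stayed close. Some of them could hardly change a result. Requiring at least 100 bp removed only 100 of 11436 peaks. Both that setting and the use of peaks at or above the median width kept the same 108 wide peaks. Close means within 1.5 times for the number of dense clusters, and within the 95% binomial interval for the share at 306 bp. The outer to inner density ratio ranged from 1.88 to 2.303, and the inner minus outer width from 21.9 to 32.3 bp. The clustering fold ranged from 1.56, with peaks within 1 kb merged, to 2.81 among the peaks at or above the median width. It was 1.63 with placement within windows of 100 kb. The share of wide peaks in the inner part ranged from 45.2%, counting from 1 kb, to 64.3%, counting from 3 kb. The other peaks had 31.9% and 32.4% there. The outer minus inner share at 306 bp ranged from 4.45 to 4.69 percentage points, and the scaffold minus chromosome width from 31 to 67 bp. With 1 wide peak kept per window of 1 Mb, the inner share was 54.8%, against 32.3% of the other peaks (Fisher's exact p = 0.00032). The other peaks were not thinned in this way, so that test set windows against single peaks. Since the inner and outer parts are equal in length, its p-value does not show that windows with a wide peak favour the inner part. Without chromosome 13 the density ratio was 2.25 ± 0.59 (SD, n = 19).

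The number of dense clusters, 15, became 23 with gaps of up to 20 kb, 10 with gaps of up to 5 kb, 7 after merging peaks within 1 kb and 8 among the peaks at or above the median width. The share of peaks at 306 bp was 16.1% on chromosomes alone, where the scaffold peaks, fewer of which have this width, are left out. Depth was unknown, so its effect on any result was not tested.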

Other observations

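All tests in this part were chosen after the peak list had been examined, and only those of random cluster placement and of the width difference among peaks over 308 bp were set down before their own result was seen.

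Some scaffolds carried many peaks. Scaffold 86 held 2 dense clusters, with 19 peaks from 80422 to 139359 and 8 from 50159 to 63860. Scaffold 245 held 12 peaks, 8 of them between 4622 and 29743, and scaffolds 38 and 39 held 16 and 15. In all, 8 scaffolds had 10 or more peaks. A peak began at the first base on 11 scaffolds and on chromosome 1, where it ended at 642.

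The smaller dense clusters lay on chromosome 9 from 30590877 to 30618865 (9 peaks), and on chromosomes 6, 11 and 18 with 8 peaks each. Those ran from 42866424 to 42887188 on chromosome 6, from 33306440 to 33328894 on chromosome 11 and from 41621154 to 41636404 on chromosome 18. On chromosome 18 the median width was 1123 bp and peaks covered 58.7% of the cluster, against 491.5 bp and 18.3% on chromosome 11.

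The excess of peaks at exactly 306 bp may come from a smallest width set during peak calling. There were 79.9 times as many peaks at this width as at the median of the 10 widths below it, which held 22 peaks per width. That value restates the excess that prompted the explanation and does not decide it, since the peak-calling settings are not given in the sources used here. Peaks under 306 bp, 12.3% of the list, could be partial overlaps between peaks of the replicates, but the replicates' own lists were not used here, so this cannot be told apart from other sources either. The lower share of this width on scaffolds and in the inner part of chromosomes stays open. No biological explanation was tested, since the design holds 1 tissue and stage.

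The 12 dense clusters on chromosomes argue against chance spacing inside windows of 1 Mb, since 200 random placements gave at most 1. To look for intact copies of one sequence that share their peak spacing, the peaks of pairs of clusters were lined up. At most 4 peaks lined up within 10 bp among 105 pairs of the 15 clusters, and reordered gaps gave 4 to 6 (permutation p = 1 with 200 reorderings). Over all 15 clusters this does not decide, because small planted copies were often missed. Among the 4 clusters of at least 25 peaks the most was also 4. Planted copies of 25 peaks with midpoints moved by up to 50 bp lined up 6 to 14 peaks, and 79 of 80 exceeded the reordered range. This argues against intact copies of at least 25 peaks moved by up to 50 bp. Apart from these moves, each planted copy kept all its peaks at a constant offset. Copies with lost peaks, or with inserted or deleted sequence, therefore stay open. Smaller copies were planted from the largest cluster alone. Those of 15 peaks exceeded the range in 20 of 20 cases when moved by up to 20 bp and in 5 of 20 by up to 50 bp. Those of 8 peaks did so in 20 of 20 cases by up to 4 bp, 2 of 20 by up to 20 bp and 0 of 20 by up to 50 bp. Copies of 15 peaks moved by up to 50 bp, and of 8 peaks moved by up to 20 or 50 bp, therefore stay open. Diverged repeats, insertions of organelle DNA, a copy number in the plants above that of the reference, and wide domains of open chromatin remain untested, since neither sequence nor read signal was used, and no biological explanation was tested.

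The wider peaks in the inner part of chromosomes were weighed against the dense clusters alone and against a different share of peaks at the commonest widths or below. Without the dense clusters the inner median was higher by 21.85 ± 28.3 bp on average and on 16 of 20 chromosomes (permutation p = 0.0033). Among peaks over 308 bp it was higher by 21.98 ± 39.5 bp and on 14 of 20 chromosomes (permutation p = 0.021). Both values argue against these explanations as the whole cause. Depth, repeats that limit where reads can be placed, and a biological source were not tested.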
